A study of Mus musculus with 2 samples.

How the data were processed

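The single hearts of 2 B6NCrl mouse pups on postnatal day 0, from 1 litter, were measured by small RNA sequencing, with 1 library per heart. Sex was not collected. Per the labels, total RNA was used, inserts were under 30 nt and reads were placed on mouse assembly mm10; the deposited description of each library names GENCODE M4 as the annotation. The deposited values were counts, whole numbers of reads per miRNA gene, not normalized, in 3 columns: both strands, the sense strand and the opposite strand. The first was the exact sum of the other 2 in all 1973 genes. The aligner, counter, adapter trimming, mismatch and multiple-alignment settings were not given in the sources used here, and no step after counting is recorded. Counts are per gene, so the 2 arms of a precursor are not separated.

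The tables opened with 4 summary rows, which were kept out of library sizes and tests. They held 11.5% of reads in replicate 1 and 10.5% in replicate 2 as unmapped, 36.6% and 37.1% as aligned to several places, 5.93% and 5.62% as on no feature of the sense strand, and 0 as ambiguous. Reads aligned to several places are not resolved by gene, which can lower the count of a miRNA with near-identical loci, such as Mir1a-1 and Mir133a-1. The sense strand column had the larger total and was used; it held 46.0% and 46.9% of reads. The opposite strand held 6.62% and 6.67% of the counts on genes and is treated in the closing section. No per-sample column was left unused for want of a label.

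Positions, host genes and sequences came from GENCODE M21, which is on GRCm38, the same assembly as mm10. Of 1973 gene identifiers, 1894 matched and 79 did not; the 79 had 0 counts. Genes were marked as sharing sequence when a stretch of 20 nt of the annotated precursor occurred in another miRNA gene (929 of 1894), and as numbered copies when symbols differed only by a final number (118). Such genes are reported as uncertain, where they are named or in 1 sentence of the report. Genes that overlap on the genome were not compared with each other. Mir126a, Mir30e, Mir451a and Mir486 were thus not checked against the miRNA gene on their opposite strand.

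CPM was computed over the sense counts on miRNA genes, scaled to 1000000, and a gene was called detected at 2 CPM. Shares have exact Clopper-Pearson 95% intervals per library, and a count of 0 was read as up to 3 counts. Log2 ratios between pups used a pseudocount of 1 CPM. Gene lists (20 lists, 226 symbols of which 199 had a row, counting older names; the others have no value in the sense counts, and 11 of the 12 miRNAs seen on opposite strands are among them) were fixed before the data were examined, as were the tests, the pairs of genes and the alternatives, except those said to be added later. Mir486 stands in both the muscle and the erythroid list. The rule for named genes took the 20 most abundant, up to 4 of the most abundant members of each list, all muscle list members and pair members, and the 5 genes with the largest log2 ratio in each direction among those with a mean of 50 CPM or more; the text names most but not all of them. Genes outside the rule were named after their values were seen: those past 1.5-fold with a lower mean, Mir667, the brain miRNAs at 0 counts, miRNAs on opposite strands, and cluster members in the closing section. The pair of Mir195a and its cluster partner was not computed, for want of a sense count of the partner.

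The 2 libraries were compared by an exact two-sided binomial test per gene, given TMM-scaled library sizes, with Benjamini-Hochberg adjustment at 0.05. It compares 2 libraries, not conditions. The coefficient of variation between pups is the square root of edgeR's common dispersion in an intercept-only model over genes with 10 or more counts in both. A list's median log2 ratio was set as a percentile among 10000 random lists matched by deciles of mean expression, which describes these libraries and is not a p-value. Random lists were not matched on genomic clusters, whose members may vary together. Both pups come from 1 litter, so the spread between them does not cover litters, and library preparation and animal cannot be separated with 1 library per heart.

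The methods were tested on simulated data. Simulated coefficients of variation of 0, 5, 10 and 20% came back as 0.988, 5.24, 9.53 and 19.9%. All genes of a simulated set had the same value. The recovery was thus not tested for data in which few genes carry much of the spread, as Mir449a does here. For the exact test between the 2 libraries (581 genes), 33.0% of 100 genes changed 1.5-fold and 51.0% of 100 genes changed 3-fold were called. Among genes with a mean of 50 CPM or more, these were 96.2% of 26 and 100% of 33. Of 415 unchanged genes 0.723% were called, and of the 133 with a mean of 50 CPM or more 2.26%. Alternatives covered detection limits, pseudocounts, scaling by total counts or DESeq2 size factors, DESeq2 dispersions, thinning of the deeper library (20 draws), counts of both strands, removal of numbered copies or of the most abundant gene, and each pup alone. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.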

Results

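MicroRNAs (miRNAs), the short RNAs that repress messenger RNAs, were sequenced from the heart of newborn mice of strain B6NCrl on postnatal day 0. The series held 1 group of 2 samples, each the single heart of 1 pup: pup 2 gave replicate 1 and pup 3 gave replicate 2, and both came from the litter of pregnant female 1. The libraries were made from total RNA with inserts under 30 nt. Replicate 1 had 5052766 reads and 2323450 counts on the sense strand of miRNA genes. Replicate 2 had 7441784 reads and 3487183 such counts. With 1 group there was no comparison between conditions. The questions that the design allowed were which miRNA genes the newborn heart contained, at what share, and how far 2 hearts of 1 litter differed. Values are given as the share of sense counts or as CPM, the count scaled to a fixed total of 1000000 sense counts, with the SD over the 2 pups (n = 2). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Shares and ratios between genes compare counts. How many reads each miRNA yields per molecule was not measured, so the SD over the pups does not cover error in such comparisons. Positions are on GRCm38.

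A few miRNA genes held most of the counts in the newborn heart. Mir126a, the miRNA of endothelial cells, was the most abundant at 10.7% ± 0.177 (SD, n = 2), and Mir143, the miRNA of smooth muscle, followed at 9.86% ± 0.271. Mir335, which lies in an intron of the imprinted gene Mest, took 7.58% ± 0.402. Mir208b, which lies in an intron of the beta-myosin heavy chain gene Myh7, took 6.98% ± 0.049. Mir99a reached 6.68% ± 0.219 and Mir322, on the X chromosome, 5.75% ± 0.0461. The 10 most abundant genes, which also included Mirlet7g (4.78% ± 0.0205), Mir30e (4.59% ± 0.0204), Mir26b (3.34% ± 0.116) and Mirlet7i (3.23% ± 0.0475), held 63.5% ± 0.441 of the counts. This order covers only genes with a row of their own. Mir378a has none, and the reads on its strand, 6.13% ± 0.0109 of the sense total, would rank 6. The order also leaves out reads aligned to several places, 36.6% of reads in replicate 1 and 37.1% in replicate 2. A miRNA with near-identical loci may therefore rank too low, and the true order is uncertain.

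The next 10 genes raised the held share to 82.1%. They were Mir23a (2.62% ± 0.171), Mir22 (2.22% ± 0.117), Mir23b (2.20% ± 0.160), Mir21a (2.06% ± 0.176), Mir351 (1.94% ± 0.330), Mir30a (1.77%), Mir130a (1.61% ± 0.0837), Mir30d (1.54% ± 0.0401), Mir208a (1.49% ± 0.140) and Mirlet7d (1.23% ± 0.0525). The exact Clopper-Pearson 95% interval of the Mir126a share was 10.8% to 10.9% in replicate 1 and 10.5% to 10.6% in replicate 2, so counting error was smaller than the spread between pups. In all, 327 of 1973 miRNA genes reached 2 CPM in both hearts, 349 did so in replicate 1 and 339 in replicate 2. Of the genes named here, Mir23a, Mir23b, Mir27a, Mir16-1, Mir411, Mir487b, Mir302a, Mir302b and Mirlet7c-1 share a stretch of 20 nt or more with another miRNA gene and are uncertain in the same way as those marked where they are named. A count of 0 allowed a level of up to 1.29 CPM in replicate 1 and 0.860 CPM in replicate 2.

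**Figure D1:**
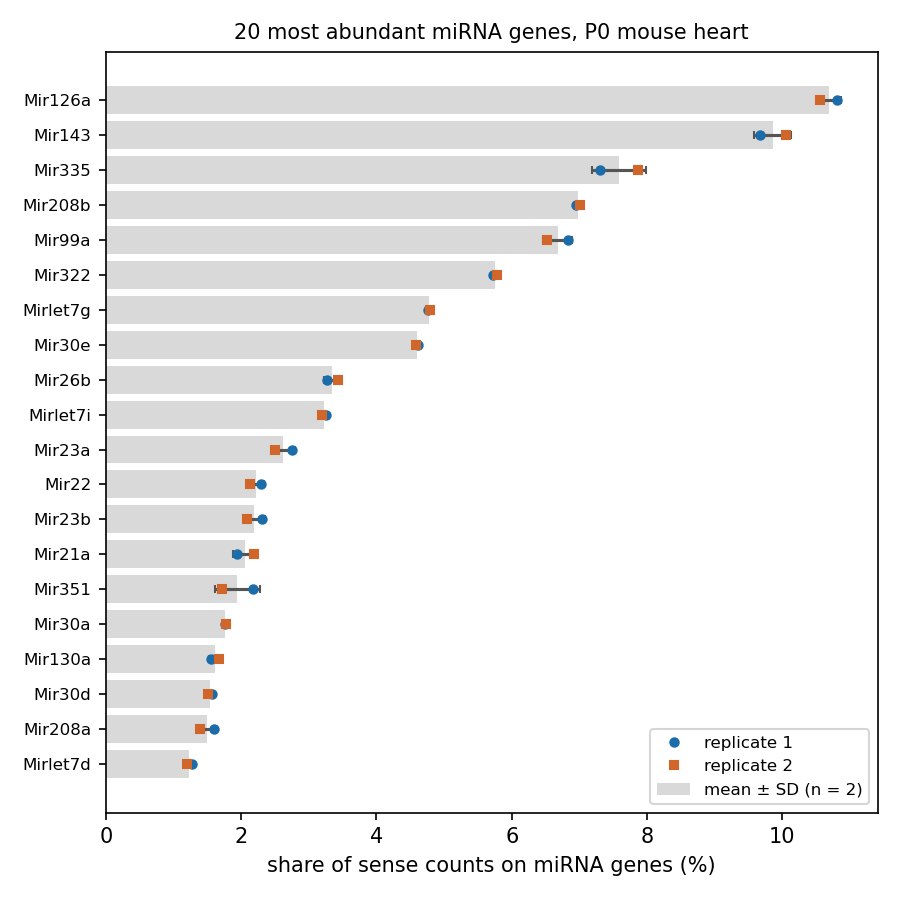
Share of sense counts on miRNA genes, in percent, for the 20 most abundant genes with a row of their own, which leaves out Mir378a. Reads aligned to several places were assigned to no gene and are also left out. Bars are the mean of the 2 pups, error bars the SD (n = 2), circles replicate 1 and squares replicate 2. Mir126a (10.7%) and Mir143 (9.86%) lead, and Mir335 (SD 0.402) and Mir351 (SD 0.330) show the widest spread between pups.

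Mir126a lies at chromosome 2, 26591357 to 26591429, plus strand, inside Egfl7, where at least 1 annotated exon of that gene overlaps it. Its 73-nt annotated precursor is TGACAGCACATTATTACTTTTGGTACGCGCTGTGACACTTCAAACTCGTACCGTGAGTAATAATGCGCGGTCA. Mir335 lies at chromosome 6, 30741299 to 30741396, plus strand, in an intron of Mest, with the 98-nt precursor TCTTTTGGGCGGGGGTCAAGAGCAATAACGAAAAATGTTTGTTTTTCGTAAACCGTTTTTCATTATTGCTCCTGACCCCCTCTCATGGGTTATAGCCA. Mir208a lies at chromosome 14, 54949060 to 54949142, minus strand, in an intron of the alpha-myosin heavy chain gene Myh6, with the 83-nt precursor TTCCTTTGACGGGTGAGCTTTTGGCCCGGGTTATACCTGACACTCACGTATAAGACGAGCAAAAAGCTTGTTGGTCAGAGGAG. Mir208b lies at chromosome 14, 54975700 to 54975776, minus strand, in an intron of Myh7, with the 77-nt precursor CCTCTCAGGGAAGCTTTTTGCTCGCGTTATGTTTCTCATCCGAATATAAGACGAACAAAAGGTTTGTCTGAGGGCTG.

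Among the miRNAs of cardiac and skeletal muscle, those hosted by myosin genes carried nearly all of the counts. In sense counts, Mir208b was 4.68-fold higher than Mir208a (log2 ratio of Mir208a over Mir208b -2.23 ± 0.145, SD over 2 pups). Mir499, in an intron of Myh7b, took 0.479% ± 0.00757. The 10 measured members of the list held 8.96% ± 0.085 together. Mir1a-1 and Mir133a-1, which belong to the classical muscle miRNA families, were counted far lower: Mir1a-1 had 17 counts in replicate 1 and 19 in replicate 2, and Mir133a-1 had 20 and 25.

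Mir133a-2 and Mir133b each had 5 counts in replicate 1 and 7 in replicate 2, Mir1b had 7 and 9, Mir206 had 61 and 58, and Mir486, which is also expressed in red cells, had 181 and 230. Mir1a-2 had no row of its own, but 98 and 152 reads lay on its strand in the row of Mir1b, which it overlaps. The log2 ratio of Mir1a-1 over the Mir133a loci was -0.65 ± 0.138 on sense counts, and with the reads on the strand of Mir1a-2 added to Mir1a it turned to 2.31 ± 0.153, or 4.96-fold in favour of Mir1a. The log2 ratio of Mir133b over Mir206 was -3.33 ± 0.395. The values of Mir1a-1, Mir1b, Mir133a-1, Mir133a-2 and Mir133b are uncertain, because each shares a stretch of at least 20 nt with another miRNA gene and 36.8% of all reads aligned to several places and were assigned to no gene. Mir486 is uncertain as well, since it was not checked for sequence shared with Mir3107, which overlaps it on the opposite strand. No test of these ratios was made, since an exact two-sided sign flip over 2 pups, the test set for them, cannot give p below 0.5.

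Markers of other cell types of the heart were led by the 2 most abundant genes. The endothelial list (Mir126a, Mir221 and Mir222 measured) held 10.7% ± 0.176, of which Mir221 and Mir222 contributed 0.0121% and 0.0057%. The smooth muscle list held 10.03% ± 0.274, nearly all from Mir143, which exceeded its cluster partner Mir145a in sense counts by a log2 ratio of 5.85 ± 0.00737. The fibroblast and mesenchymal list held 2.30% ± 0.190, led by Mir21a at 2.06%, with Mir214 at 0.181% ± 0.00494 and Mir29a at 0.0347% ± 0.00626. Mir21a, the Mir29 genes, Mir221 and Mir222 are widely expressed, so their counts do not mark a single cell type. The Mir199 genes together lay below Mir214, with a log2 ratio of -3.36 ± 0.127, and their loci share sequence and are uncertain. Mir126a and Mir143 differed by a log2 ratio of 0.12 ± 0.0635.

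Blood miRNAs took small shares. The erythroid list held 0.0656% ± 0.00686, with Mir451a at 0.0424% ± 0.00199, Mir144 at 0.0160% ± 0.00402 and Mir451a over Mir486 at a log2 ratio of 2.57 ± 0.102. That ratio is uncertain, since neither gene was checked for sequence shared with the miRNA gene on its opposite strand. The white blood cell list held 0.0575% ± 0.00222, with Mir223, the myeloid miRNA, at 0.0329% ± 0.000835, Mir155 at 0.0161% and Mir150 at 0.00273%; Mir142 has no row of its own, and the reads on its strand in the row of Mir142b (0.0603% ± 0.0109) would bring the list to 0.118% ± 0.0131.

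Among the lists of miRNA families, let-7 held the largest share of sense counts. Reads aligned to several places were assigned to no gene, so the true order of the families is uncertain. The let-7 and miR-98 list held 10.2% ± 0.081, and its median level exceeded that of 99.8% of 10000 random lists of the same size. The miR-30 list held 7.94% ± 0.0567, led by Mir30e. The list of Mir15, Mir16 and relatives with the same seed held 6.72% ± 0.0436, mostly from Mir322, with Mir16-1 at 0.283% ± 0.00888 and Mir15a at 0.237% ± 0.00652. The miR-23/27/24 list held 5.16% ± 0.322, in which Mir27a took only 0.0628% ± 0.00169 beside Mir23a, its neighbour in the same cluster. The miR-26 list held 3.35% ± 0.116, nearly all from Mir26b; Mir26a-1 and Mir26a-2 share sequence and are uncertain. The miR-378 and miR-22 list held 2.22% ± 0.117 on sense counts, nearly all from Mir22; reads on the strand of Mir378a, which has no row of its own, would bring it to 8.35% ± 0.106 of the sense total.

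The growth-associated miR-17~92 and paralogous clusters held 2.09% ± 0.0592, with Mir17 at 0.857% ± 0.0211 and Mir93 at 0.347% ± 0.0141. In sense counts, which leave out reads aligned to several places, the let-7 sum exceeded this sum 4.86-fold (log2 ratio 2.28 ± 0.0523). Mir17 exceeded Mir20a by a log2 ratio of 1.34 ± 0.0406. The Dlk1-Dio3 imprinted region of chromosome 12 held 1.96% ± 0.206, with Mir411 at 0.356% ± 0.031 and Mir127 at 0.289% ± 0.0242. The miRNAs hosted by H19 and Igf2, a pair of imprinted fetal growth loci, held 0.182% ± 0.0206, of which Mir483 in Igf2 took 0.176% ± 0.0207 and Mir675 in H19 0.00593%. The Hox cluster list held 0.271% ± 0.013, from Mir10b (0.139% ± 0.00481) and Mir10a (0.127% ± 0.0177).

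miRNAs of other tissues were present at low shares. The liver list held 0.0278% ± 0.00187, or 0.0126% without numbered copies, with Mir122, the liver miRNA, at 125 counts in replicate 1 and 165 in replicate 2. The brain list held 0.0337% ± 0.000777, and its neuronal members Mir9-2, Mir9-3, Mir124a-1, Mir124a-2 and Mir124a-3 had 0 counts in both hearts; each shares 26 to 33 nt with another locus, and reads that aligned to several places were assigned to no gene, so the level is uncertain. The pluripotent cell list held 0.0155% ± 0.000734, with Mir302a at 121 and 225 counts and Mir302d at 100 and 151. The epithelial, lung and gut list held 0.154% ± 0.0486, and was the list whose share differed most between the pups relative to its level, at 0.119% in replicate 1 and 0.188% in replicate 2.

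Of 193 genes with a mean of at least 50 CPM, 187 (96.9%) lay within 1.5-fold, and the median absolute log2 ratio was 0.11. Mir449a, the miRNA of multiciliated cells, in an intron of Cdc20b, stood furthest apart, with 83 counts in replicate 1 and 2589 in replicate 2, 20.8-fold higher in CPM. Mir200c, an epithelial miRNA, was 4.36-fold higher in replicate 2, and Mir429, Mir34c and Mir200b were 2.44-fold, 2.39-fold and 2.02-fold higher. The reverse direction held 1 gene past 1.5-fold, Mir181a-2, with 462 counts in replicate 1 and 348 in replicate 2, a gene that shares sequence with another locus.

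Across 361 genes at 2 CPM or more in either heart, Pearson's r of log2(CPM + 1) was 0.989 (0.983 to 0.993 over 1000 resamples of genes) and Spearman's rho was 0.985 (0.976 to 0.991); genes are not independent replicates. A chi-square of the counts, set as the check for 1 library deposited as 2, was 33.0 per degree of freedom (309 degrees of freedom). The libraries thus differed beyond counting error, and the labels give them as 2 pups. An exact two-sided binomial test per gene with Benjamini-Hochberg adjustment, which compares these 2 libraries at counting error only, found 86 of 615 genes to differ, 55 higher in replicate 2 and 31 lower. Of these, 18 also passed 1.5-fold, 17 higher and 1 lower. For abundant genes the test passed on very small differences: Mir335 was 1.08-fold higher in replicate 2. The coefficient of variation between the pups beyond counting noise was 18.6% over 298 genes (10.5% to 26.2% over 100 resamples of genes). It was 13.5% without Mir449a, and 10.3% over the 196 genes with 100 or more counts in both. The median of DESeq2's estimates per gene, a different summary, was 0.594% over the same 298 genes.

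**Figure D2:**
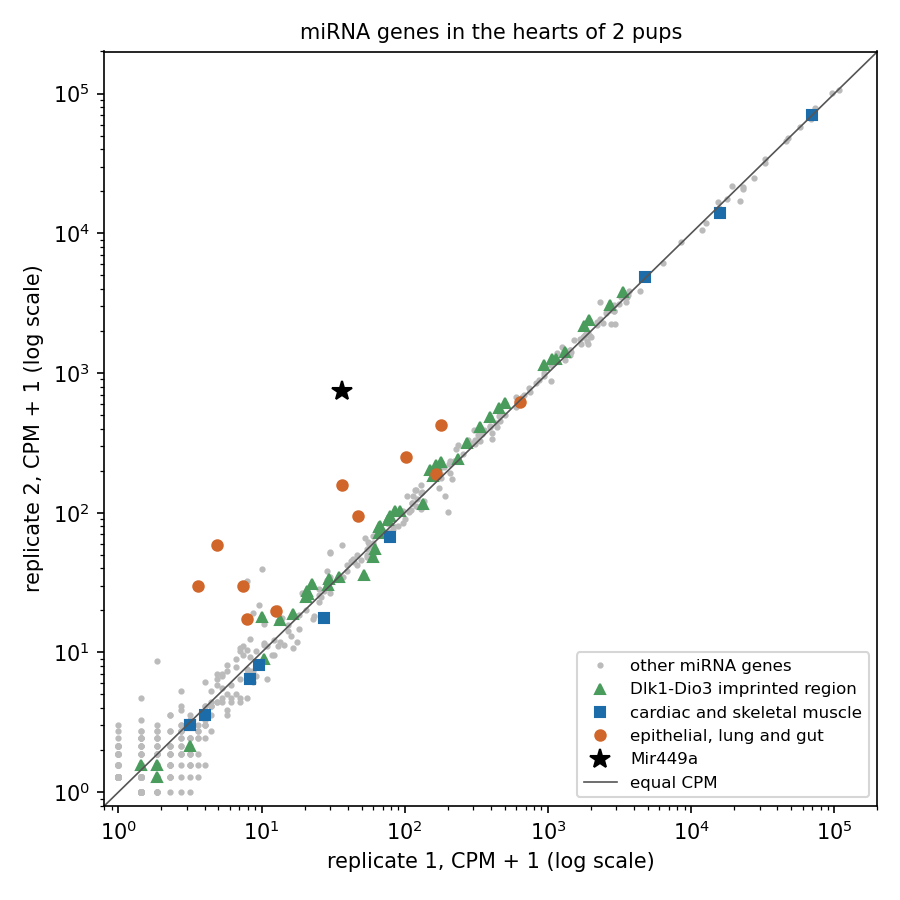
CPM + 1 of each miRNA gene in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales; squares, triangles and circles are the muscle, Dlk1-Dio3 and epithelial lists, the star is Mir449a and the line marks equal CPM. Mir449a stands off the line at 35.7 and 742 CPM, and 10 of the 11 epithelial miRNAs lie above it.

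miRNAs of epithelia were higher in replicate 2 as a group. Their median log2 ratio was 1.25, or 2.38-fold, 10 of the 11 measured members were higher, and the median exceeded those of all 10000 random lists matched on mean expression. By the exact test 8 of the 11 were higher and 0 lower, and 10 were higher with p adjusted over the list alone. Mir375, a neuroendocrine and gut miRNA, went from 9 counts in replicate 1 to 200 in replicate 2 (14.8-fold, adjusted p = 2.74e-31, exact binomial test), and Mir205, a miRNA of stratified epithelia, from 6 to 101 (11.2-fold, adjusted p = 1.71e-14, exact binomial test). Mir141 and Mir34b were also higher, at 4.44-fold and 2.37-fold. Mir375, Mir205, Mir141 and Mir34b were named after their values were seen. Mir200b and Mir429, Mir200c and Mir141, and Mir34b and Mir34c are genomic neighbours. Such neighbours may vary together, which random lists matched on expression do not model. The list's most abundant member, Mir215, did not pass the test, with 1480 and 2159 counts (log2 ratio -0.04), and neither did Mir203, with 380 and 660.

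Outside that list, the genes past 1.5-fold and higher in replicate 2 were Mir449a, Mir182, Mir183, Mir96, Mir137, Mir7b, Mir92b, Mir338 and Mir193b; apart from Mir449a they were named because they passed, after their values were seen. Mir137 and Mir7b belong to the brain list, whose other tested members did not pass. With p adjusted over that list alone, 2 members were higher and 1 lower. The list's median log2 ratio was -0.01, but it rests on numbered copies, which are uncertain. Mir137 and Mir7b were its only members with a ratio that are not numbered copies. The liver list, with a median of -0.13, had no called member among 4 by the exact test.

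miRNAs of the Dlk1-Dio3 imprinted region were also higher in replicate 2, by less. Their median log2 ratio was 0.23, or 1.17-fold, with 34 of 41 members higher, and the median lay at percentile 99.985 of the random lists. Many members are neighbours on chromosome 12 and may vary together, which random lists matched on expression do not model. The exact test called 16 of 44 higher and 1 lower, and 17 and 1 with p adjusted over the list alone. Mir487b (log2 ratio 0.30), Mir379 (0.27), Mir411 (0.18) and Mir127 (0.17) were higher, and Mir667 (-0.55), named after its value was seen, was lower. No member of this list passed both the exact test and 1.5-fold.

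In the erythroid list, Mir144 was lower in replicate 2 by the exact test (log2 ratio -0.51), while Mir451a (-0.10) and Mir486 (-0.24) did not pass, and the list median of -0.24 lay at percentile 0.945. In the muscle list, whose median was -0.18 at percentile 5.4, Mir208a was lower (-0.19), Mir208b (0.01) and Mir499 (0.03) did not pass, and 2 of 10 members were higher. That median rests partly on low counts. Mir1a-1, Mir1b, Mir133a-1, Mir133a-2 and Mir133b had at most 25 counts in either library, share sequence and are uncertain. Mir351 (-0.35) and Mir423 (-0.38) were lower among the genes with the largest differences, and Mir505 (-0.31) did not pass. The remaining lists had medians between -0.25 (miR-378 and miR-22) and 0.10 (miR-17~92 and miR-26). The endothelial median was -0.01, the smooth muscle median 0.05, the fibroblast median 0.09 and the white blood cell median -0.10, with all 10000-list percentiles of these 4 between 4.48 and 83.0.

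**Figure D3:**
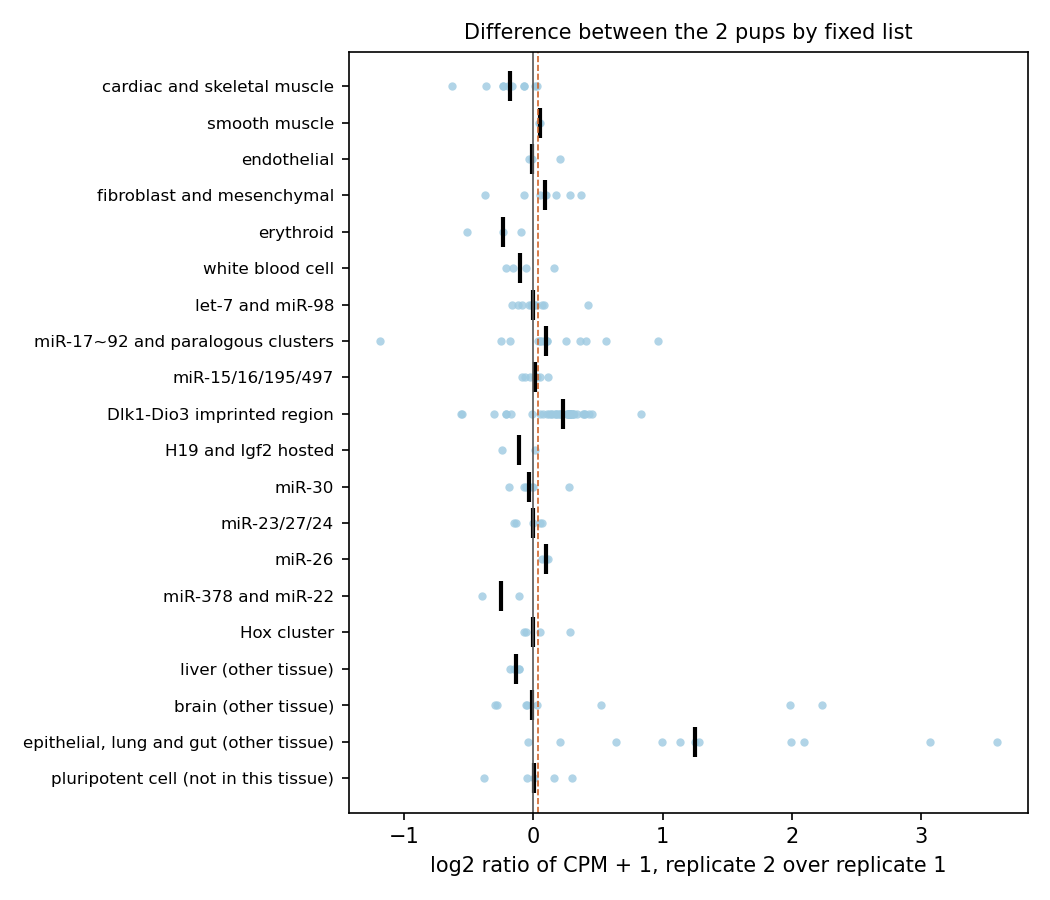
Log2 ratio of CPM + 1, replicate 2 over replicate 1, for each member (dots) and the median (black bars) of the 20 fixed lists; the solid line marks 0 and the dashed line the median of all detected genes. The epithelial list stands apart with a median of 1.25, and the Dlk1-Dio3 list has a median of 0.23.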

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

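All tests of explanations in this part were chosen after the results were seen. With 2 samples in 1 group, there was no test of a sample as an outlier and no effect to compare between groups, so the results below come from data outside the sense counts, plus the 2 patterns of the report that most call for a second look. No biological explanation was tested, since the design has 1 group.

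In all, 12 rows carried reads on the strand opposite to their gene, with at least 50 such counts in both libraries, far above the 1.29 and 0.860 CPM that a count of 0 allows, and held 99.97% of all opposite-strand counts. Opposite to Gm25301 lies Mir378a, a miRNA hosted by the metabolic regulator Ppargc1b, with 61320 CPM ± 109 (SD, n = 2), which would rank 6 among the sense genes. Opposite to Gm25927 lies Mirlet7e (2814 CPM), opposite to Gm24083 Mir191 (2556 CPM), opposite to Gm24321 Mir409 (965 CPM), opposite to Gm25252 Mir376a (868 CPM), opposite to Mir497b Mir497 (792 CPM), opposite to Mir299b Mir299a (680 CPM) and opposite to Mir142b Mir142 (603 CPM). The last 4 pairs are Gm25750 with Mir380 (323 CPM), Gm24111 with Mirlet7f-1 (106 CPM), Mir3074-1 with Mir24-1 (48.3 CPM) and Mir1b with Mir1a-2 (42.9 CPM). Reads aligned to several places, also not resolved by gene, made up 36.8% of reads.

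A candidate explanation for the opposite-strand reads is an annotated miRNA gene on that strand without a row of its own in the tables used here. All 12 rows (100%) overlap such a gene, against 20 of the other 1961 rows (1.02%), which is in line with this explanation. Strand errors in the libraries are argued against, because on the 26 genes with 10000 or more sense counts in both hearts the opposite strand held 0.00032% of the sense reads. The sense shares in the report leave out Mir378a and the other 11 miRNAs.

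Epithelial miRNAs and Mir449a were higher in replicate 2. Library size or scaling is argued against, since a wrong scale moves every gene by 1 factor and the 350 detected genes outside the list had a median log2 ratio of 0.033 (quartiles -0.15 and 0.18), against 1.25 for the list. Counting noise is argued against, since 72.7% of the 11 members of a list fixed before the data were examined passed the exact test. Tissue or RNA of another organ in 1 sample may be a source, and stays open: with 1 library per heart, a difference of dissection, of library or of the heart itself cannot be told apart. All 11 members were at 2 CPM or more in both hearts and stand in no other list, and the most abundant, Mir215, did not pass the test (log2 ratio -0.04).

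Mir1a-1, Mir133a-1 and other muscle miRNAs with several loci had few counts, also with the 42.9 CPM on the strand of Mir1a-2. Reads shared between near-identical loci are a candidate explanation: the 60 list genes that share a stretch of 20 nt, those at 0 included, had a median of 31.1 CPM and the 124 that share none 94.3 CPM, a difference of medians of -1.60 on the log2 scale (permutation p = 0.0185, 100000 resamples). This lies short of the difference of 2 set as decisive. The genes came from all lists, those of other tissues included, and were permuted as if independent. The permutation p therefore does not separate shared sequence from a low level in the tissue. Mir1a-1 shares 28 nt with Mir1b, and Mir133a-1 shares 31 nt with Mir133a-2, against inserts under 30 nt. A read inside such a stretch aligns to both loci and was assigned to neither. The tissue level of these miRNAs was therefore not measured, because the 36.8% of reads that aligned to several places are not resolved by gene. A low level in the tissue also stays open, and the explanations cannot be told apart here.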

How the results depend on the processing

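Of 244 values of the summary results under another setting, 186 moved by less than the spread used for each or stayed within 1.5 times for counts. In 8 the sign changed: the Mir1a over Mir133a pair, and 7 values of list medians between pups that lay within 0.0164 of 0 (miR-15/16, Hox, pluripotent and brain). Each pup alone is not among these, since with 2 pups each lies within 1 SD of the mean by construction; the detected genes numbered 339 in replicate 2 alone and 349 in replicate 1 alone. The alternatives without the epithelial list or Mir449a, and with opposite-strand miRNAs, were added after the data were seen. No paired analysis was possible because there is 1 group. The cause was not tested unless stated. Depth limits the calls: below 50 CPM the exact test misses most 1.5-fold differences in simulated data.

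Leaving out the most abundant gene, Mir126a, raises other shares by construction. The 10 leading genes then held 62.04%, and the lists held 10.04% (muscle), 11.2% (smooth muscle), 0.020% (endothelial), 2.58% (fibroblast), 0.0735% (erythroid), 0.0644% (white blood cell), 11.4% (let-7), 2.34% (miR-17~92), 7.52% (miR-15/16), 2.19% (Dlk1-Dio3), 0.204% (H19 and Igf2), 8.89% (miR-30), 5.78% (miR-23/27/24), 3.75% (miR-26), 2.48% (miR-378 and miR-22), 0.304% (Hox), 0.0311% (liver), 0.0377% (brain) and 0.0173% (pluripotent).

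Taking the reads opposite to another row as the list member annotated there, over the same sense total, turned the log2 ratio of Mir1a over Mir133a to 2.31, through Mir1a-2, and gave 8.35% (miR-378 and miR-22), 0.118% (white blood cell), 10.5% (let-7), 6.79% (miR-15/16) and 2.24% (Dlk1-Dio3). Counting both strands puts those reads mostly on rows outside the lists and enlarges the total, by which most list shares fall. The 10 leading genes then held 61.97%, and the lists 8.37% (muscle), 9.36% (smooth muscle), 9.99% (endothelial), 0.0537% (white blood cell), 9.50% (let-7), 1.95% (miR-17~92), 6.34% (miR-15/16), 7.42% (miR-30), 4.82% (miR-23/27/24), 3.13% (miR-26), 2.07% (miR-378 and miR-22), 0.253% (Hox), 0.0315% (brain) and 0.0144% (pluripotent). Without numbered copies the 10 leading genes held 64.18% and the lists 9.06% (muscle), 10.02% (let-7), 2.02% (miR-17~92), 6.44% (miR-15/16), 8.02% (miR-30), 0.0126% (liver) and 0.00285% (brain); the brain median log2 ratio between pups became 2.11, because Mir137 and Mir7b alone remain.

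With the single most abundant locus, the log2 ratio of Mir1a over Mir133a was -0.32 and that of Mir199 over Mir214 -3.78. With no filter, Pearson's r was 0.994 and Spearman's rho 0.895. The coefficient of variation was 10.3% with 100 counts in both and 0.594% as the median of DESeq2's estimates per gene, a different summary. The epithelial median log2 ratio was 1.14 with 10 counts in both. Genes past 1.5-fold numbered 10 without the epithelial list, against 18, since 8 of the 18 belong to it; the total was 78 against 86. The split of the 86 into 55 higher and 31 lower became 65 and 27 with total-count scaling and 47 and 39 with the deeper library thinned.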

Other observations

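The counts were concentrated in a few genomic clusters. On chromosome 18, Mir143 and Mir145a (61647825 to 61649258) held 10.03% ± 0.274 (SD, n = 2). On the X chromosome, the cluster of 7 genes from 53047997 to 53054349 held 8.24% ± 0.272, and besides Mir322 and Mir351 it includes Mir542, Mir503 and Mir450b. Within it the members differed in how they compared between pups: Mir351 was lower in replicate 2 by the exact test (log2 ratio -0.35), while Mir322 (0.02) and Mir503 (-0.03) did not pass. On chromosome 16, Mir99a and Mirlet7c-1 held 6.69% ± 0.219. By chromosome, 2 held 13.5% ± 0.0787, 14 held 10.5% ± 0.0592 and X held 10.4% ± 0.274 of the counts.

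With neighbours up to 10 kb apart on 1 strand joined, the larger Dlk1-Dio3 cluster had more genes at a mean of 2 CPM or more than any other cluster. Of its 34 genes on chromosome 12, from 109709060 to 109747960, 28 reached a mean of 2 CPM, and the 34 genes together held 1.34% ± 0.148. The Mir302 genes of pluripotent cells were counted in both hearts, with Mir302b at 89 and 129 counts and Mir302c at 17 and 29, whereas Mir367, which lies in the same cluster, had 0 in both. Of the 3 Mir449 genes in the Cdc20b intron, Mir449a had 83 and 2589 counts, while Mir449b had 0 and 4 and Mir449c 0 and 3.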
